A study of Homo sapiens with 15 samples.

How the data were processed

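RNA was measured by sequencing of poly(A)-selected libraries from undifferentiated human induced pluripotent stem cells of the line Ff-I01s01. The cells were kept for 48 h in AKM medium with IGF1 and 0, 0.5, 3 or 10 µM zinc, after 24 h of plating, with 3 libraries per dose. The labels also list 3 samples in Basic03 medium with bFGF. The table holds no column for them, so the 5 comparisons planned with that medium were not run and those samples are not analysed here.

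The authors deposited 1 table of gene signal values in 12 columns, 1 per library, with an Ensembl ID and a gene name in each of its 18948 lines. Per the labels, reads were processed with fastp 0.20.0, HISAT2 2.1.0 and StringTie 2.0.6 on the human build GRCh38.p13, and no parameters are given. The deposited signal carries no unit; it has decimals, is neither a raw count nor a complete transcripts-per-million column, and is read here as an abundance already scaled by the authors for depth and gene length. Column sums ran from 538215 to 589939. These sums are not read totals, so the depth behind each value is unknown and no counting interval is given. Cells were blank in 692 lines, and blanks were treated as missing. GENCODE release 29 held 18763 of the IDs (99.0%) and supplied positions, transcript numbers and transcript lengths.

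Values were analysed as log2(value + 1) without further scaling. The 13815 genes at 1 or more in at least 3 libraries and without a blank cell were tested; 134 genes that passed the minimum were left out for a blank. All 12 libraries entered 1 limma fit of 4 group means (lmFit, then eBayes with a trend), with R 4.3.3 and limma 3.58.1. The plan had 15 libraries in 5 groups, which the table does not hold. The comparisons were 10, 3 and 0.5 µM against 0 µM, the steps 3 against 0.5 and 10 against 3, and a moderated F-test across the 4 doses. Each was two-sided, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. Every adjusted p of a gene in the text comes from limma with Benjamini-Hochberg adjustment. Fold changes are given as log2 with the standard error of the fit, and group means are given as deposited with the standard deviation of the 3 libraries. The fold changes are of value + 1, so for low values they are smaller than the ratio of the printed means.

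Before the data were examined, 39 gene lists were fixed for zinc handling, stress responses, pluripotency and other lineages, metabolism, the cell cycle, signalling targets and organelles. The 37 lists with at least 5 measured genes were tested with camera from limma at a preset correlation of 0.01, adjusted over the 37 lists of each comparison. The same test was run with the correlation estimated per list, and fry was run as a test of whether a list moved one way. For members of a list, counts adjusted over the list alone are given beside those over all genes. The genes to be named were set by a rule of the same date. At 10 against 0 µM the rule took every called metallothionein and zinc transporter, the 8 highest and 8 lowest log2 fold changes among called genes whose groups did not overlap and whose higher mean was at least 5, and the 3 members with the smallest adjusted p of each passing list. The other comparisons took the same genes plus the 4 highest and 4 lowest by that rule. SOX2, NANOG and POU5F1 are always given. Genes outside the rule were chosen after their values were seen, and the text says so. A gene was called unstable when its value ranged at least 4-fold, on the log2(value + 1) scale, between libraries of 1 dose; 2241 genes (16.2%) were.

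Metallothionein values were also summed per library and compared by an exact permutation test, two-sided, whose smallest possible p with 3 against 3 libraries is 0.1. The pipeline was tested on simulated data in 5 runs with 200 of 13815 genes changed. Normal noise was drawn independently for each gene at its residual standard deviation, the same at every dose. The changed genes had a mean log2(value + 1) of at least log2(5 + 1). The pipeline recovered 62.9% of changes of log2 1 and 84.4% of changes of log2 2, and 3.54% of its calls were false. These rates hold for such noise only, without unstable genes, genes that vary together or a wider spread at 1 dose. The labels do not say whether the 3 libraries of a dose came from separate cultures, so the p-values may rest on technical spread. Replicate numbers were not treated as pairs. Deviations from the group means correlated between libraries of the same number at r from -0.038 to 0.042, and 3 of 12 libraries correlated best with their own number.

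The results were tested again with pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5, median-of-ratios scaling, limma without a trend, the replicate number as a block, a fit of only the compared groups, an estimated correlation for the lists, and leaving out each library in turn. Alternatives added after seeing the data were blanks read as 0, only genes that stay within 4-fold in every group, only genes with 1 annotated transcript, library weights, and removal of each library's trend with transcript length. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.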

Results

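The cells were undifferentiated human induced pluripotent stem cells of the line Ff-I01s01, kept for 48 h in AKM medium with IGF1 and a set dose of zinc. The 4 groups had 0, 0.5, 3 and 10 µM zinc, with 3 RNA sequencing libraries each. The deposited signal summed to between 538215 and 589939 per library, and the read depth behind it is unknown. Between libraries of the same dose, r across genes was 0.881 to 0.898, where genes are not independent replicates. Between libraries of different doses r was 0.854 to 0.898, so the ranges overlapped. The first principal component held 15.6% of the variance; the 3 libraries at 0 µM lay at -70.1, -41.8 and -19.8 on it, and the 3 libraries at 10 µM at 32.3, 27.1 and 25.1. Mitochondrially encoded transcripts took 31.1% ± 3.42 of the signal (SD, n = 3) at 0 µM and 34.1% ± 4.97 at 10 µM.

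The comparison of 10 with 0 µM asked which transcripts differed between the highest zinc dose and zinc-free medium. Metallothioneins, small cysteine-rich proteins that bind zinc, rose: 6 of 8 measured members passed the test and none fell. The summed signal of the 8 genes was 171.6 ± 86.1 (SD, n = 3) at 0 µM, 425 ± 95.7 at 0.5 µM, 1028 ± 76.7 at 3 µM and 1649 ± 228 at 10 µM, which was 9.61-fold over 0 µM (exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). MT1X (ENSG00000187193, chromosome 16, 56682424 to 56684196 on GRCh38) rose from 45.3 ± 21.9 to 633 ± 103, a log2 fold change of 3.88 (SE 0.30, adjusted p = 0.000513). MT2A rose from 50.7 ± 18.7 to 280.4 ± 54.1 (log2 2.50, adjusted p = 0.00186). MT1G, MT1H and MT1E rose by log2 3.84, 3.24 and 3.23, and all of these 3 varied at least 4-fold between libraries of a dose. MT1M rose by log2 1.12 (adjusted p = 0.0391), a call lost without replicate 1 of 0 µM (adjusted p = 0.0695) and without replicate 1, 2 or 3 of 10 µM (0.0731, 0.0884 and 0.11). The metallothionein list passed camera with an adjusted p of 1.99e-07 at the preset correlation, with a median log2 fold change of 2.87. With an estimated correlation its adjusted p was 0.512. In a fit of only the 6 compared libraries, MT1X was called and MT2A, MT1G, MT1H, MT1E and MT1M were not (adjusted p = 0.0628, 0.0736, 0.0937, 0.089 and 0.161).

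Zinc transporters moved in both directions at 10 against 0 µM. SLC30A1, which exports zinc across the plasma membrane (ENSG00000170385, chromosome 1, 211571568 to 211578742), rose from 3.91 ± 0.377 (SD, n = 3) to 8.48 ± 0.942, a log2 fold change of 0.95 (SE 0.12, adjusted p = 0.00291). Of 6 measured importers of the ZIP family, 3 fell (4 adjusted over the list alone). SLC39A6 fell from 32.0 ± 7.50 to 18.1 ± 1.46 (log2 -0.77, adjusted p = 0.0108). SLC39A7, which releases zinc from the endoplasmic reticulum, fell from 1.76 ± 0.236 to 0.465 ± 0.186 (log2 -0.91, adjusted p = 0.00671). SLC39A1 fell by 1.70 on the log2 scale (adjusted p = 0.0216), a call lost without replicate 1 of 0 µM (adjusted p = 0.0725) and without replicate 2 or 3 of 10 µM (0.0529 and 0.0704). The importer list had a camera adjusted p of 0.103 with a median of log2 -0.84. SLC30A9, an exporter-family member, fell from 6.46 ± 1.75 to 0.130 ± 0.162 (adjusted p = 0.0307); its values jumped within groups, and the call was lost in 5 of the 6 fits that left out 1 compared library, with adjusted p from 0.0533 without replicate 2 of 0 µM to 0.0991 without replicate 1 of 0 µM, and 0.0701, 0.08 and 0.0811 without replicates 1, 2 and 3 of 10 µM. With only the 6 compared libraries in the fit SLC30A9 was called, and SLC30A1, SLC39A6, SLC39A7 and SLC39A1 were not (adjusted p = 0.0736, 0.106, 0.089 and 0.1).

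**Figure D1:**
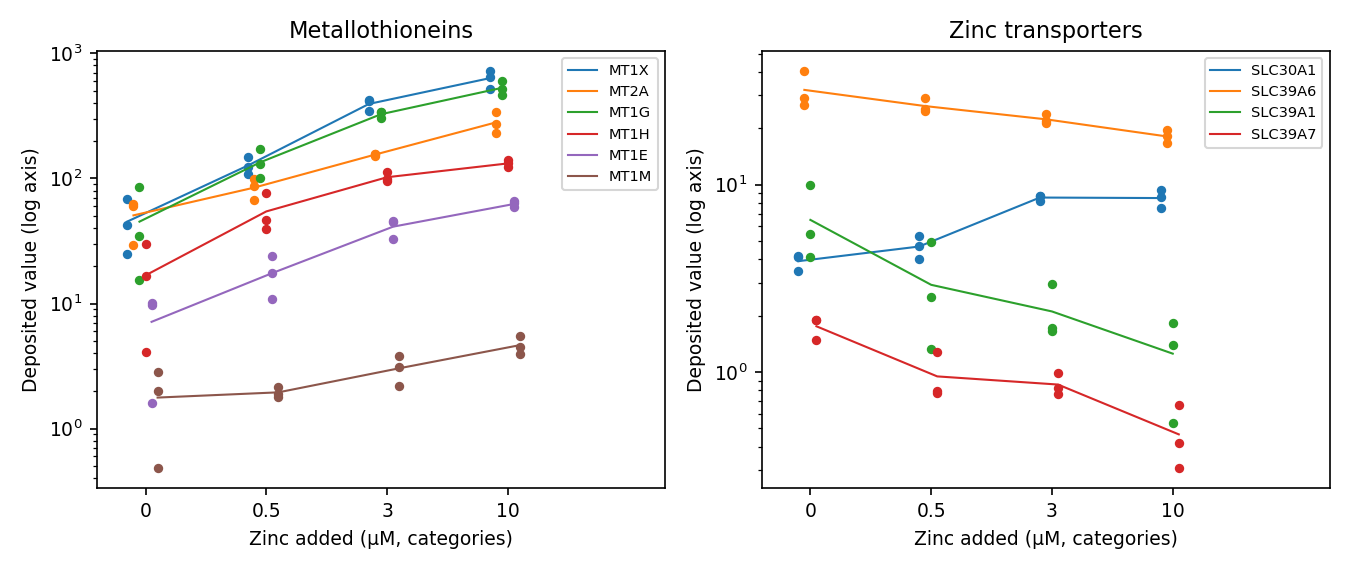
Deposited signal (log axis) of 6 metallothioneins and 4 zinc transporters in each library (points) against the zinc added in µM (spaced as categories), with lines through the group means of 3 libraries. MT1X goes from a mean of 45.3 at 0 µM to 633 at 10 µM, SLC30A1 reaches 8.54 at 3 µM and 8.48 at 10 µM, and SLC39A6 goes from 32.0 to 18.1.

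Several signalling and stress genes were lower at 10 than at 0 µM; those named here were chosen from the fixed lists after their values were seen. Among 9 measured targets of NODAL and activin, growth factors that act on human pluripotent cells, 3 fell and 1 rose (5 and 1 adjusted over the list alone). LEFTY1, a secreted NODAL antagonist, fell from 79.9 ± 28.1 (SD, n = 3) to 19.0 ± 0.974 (log2 -1.95, adjusted p = 0.00259), NODAL fell from 51.1 ± 11.5 to 25.9 ± 2.62 (log2 -0.94, adjusted p = 0.00537), and GDF3 fell by 0.65 on the log2 scale. FOXH1, a transcription factor of the same pathway, rose by 0.72 (adjusted p = 0.0108). GSC and HHEX, transcription factors of early endoderm, fell by 1.45 and 1.02. The list of NODAL and activin targets had a camera adjusted p of 0.142 and a fry adjusted p of 0.00309. At 10 against 0 µM, 15 of the 37 lists passed fry, so a pass there was not particular to this list. Leaving out any 1 of the 6 compared libraries, median-of-ratios scaling and removal of the length trend left LEFTY1, NODAL, GDF3, FOXH1, GSC and HHEX called. None of them was called with only the 6 compared libraries in the fit.

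Called genes of the endoplasmic reticulum, amino acid stress and lysosome lists were lower at 10 than at 0 µM, with sizes on the log2 scale and single genes chosen after their values were seen. Of 18 genes of the unfolded protein response, 5 fell and none rose (6 and none adjusted over the list alone). The list had a camera adjusted p of 0.121 and a fry adjusted p of 0.00248, where 15 of 37 lists passed fry. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 336 ± 46.9 (SD, n = 3) to 187 ± 3.27 (log2 -0.84, adjusted p = 0.00173), and SEL1L fell by 0.86. Of 25 targets of ATF4, a transcription factor of the integrated stress response, 7 fell and none rose (8 adjusted over the list alone; camera adjusted p = 0.0527), among them the secreted glycoprotein STC2 by 0.99. Without replicate 2 or 3 of 10 µM, 2 ATF4 targets fell. Of 23 p53 targets, 8 fell and none rose (11 adjusted over the list alone; camera adjusted p = 0.0593), among them TP53INP1 by 0.83, a call lost with the length trend removed (log2 -0.63). The number of p53 targets lower was 3 without replicate 1 of 0 µM and 3, 5 and 2 without replicates 1, 2 and 3 of 10 µM. Of 22 lysosome and autophagy genes, 7 fell and none rose (8 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.103). The number lower in that list was 4 without replicate 1 of 0 µM, and 3 and 4 without replicates 1 and 3 of 10 µM. LAMP1, a lysosomal membrane protein gene, fell by 0.86 and PSAP by 0.61. The calls of HSPA5, SEL1L, STC2, TP53INP1, LAMP1 and PSAP were lost with only the 6 compared libraries in the fit. After median-of-ratios scaling the unfolded protein response, ATF4 and p53 lists passed camera at adjusted p of 0.0465, 0.0259 and 0.0161; with an estimated correlation at the deposited scale these 3 lists had p of 0.512, 0.55 and 0.512.

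**Figure D2:**
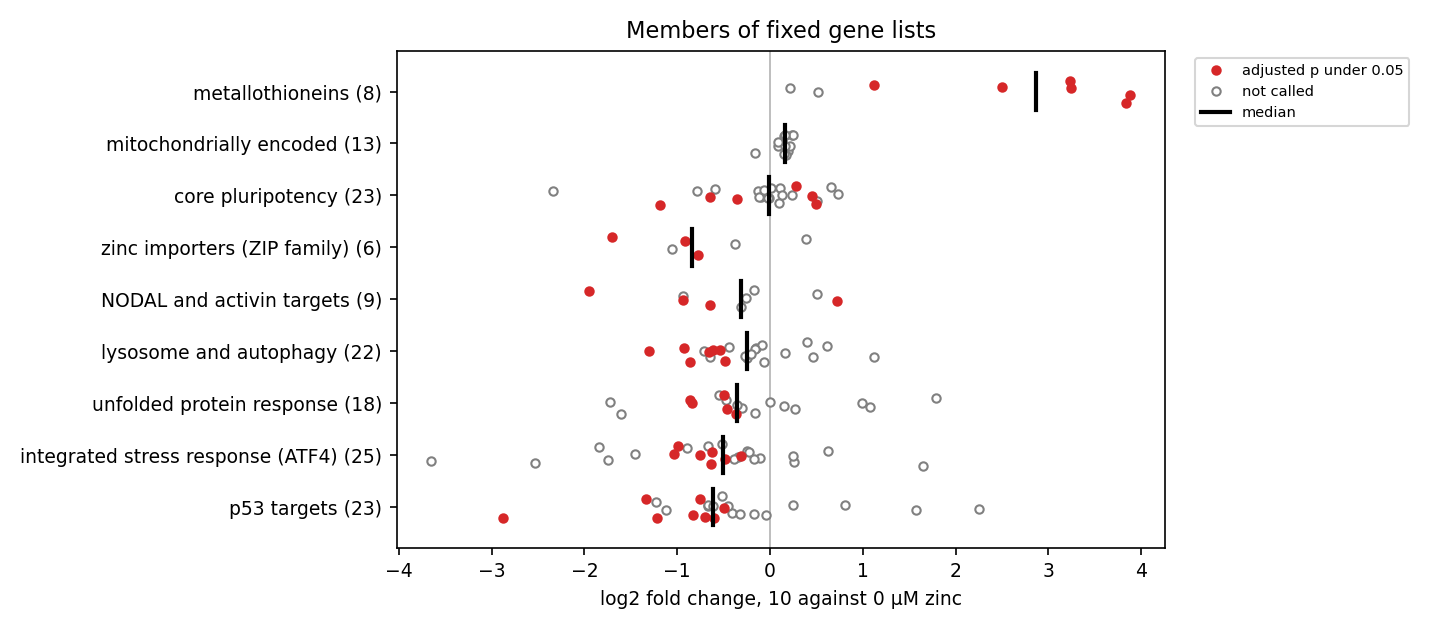
Log2 fold change at 10 against 0 µM zinc of each measured member (points, 3 libraries per dose) of 9 fixed gene lists, with members measured in brackets, filled where the adjusted p was under 0.05, and a bar at the list's median. The metallothionein median is 2.87, and no called member of the unfolded protein response, ATF4, p53 or lysosome lists lies above 0.

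Ribosomal protein genes and nuclear genes of the respiratory chain passed camera as higher at 10 than at 0 µM, by small amounts. Of 78 cytosolic ribosomal protein genes, 5 rose and 1 fell (3 rose and none fell adjusted over the list alone), with a median of log2 0.14 and an adjusted p of 0.00133; with an estimated correlation the adjusted p was 0.512. RPL36 rose from 171 ± 30.3 (SD, n = 3) to 309 ± 56.6 (log2 0.84, adjusted p = 0.00879), RPS15A by log2 0.60 and RPL26 by 0.30. Only 3 ribosomal genes rose without replicate 1 of 0 µM or 3 of 10 µM, and 9 without replicate 3 of 0 µM. The gene that fell was among RPL24, RPL29 and RPS27A, named after their values were seen. Each of these lost its call without replicate 1 of 0 µM and without replicate 3 of 10 µM (adjusted p from 0.0872 to 0.161). Of 78 genes in the respiratory chain list, 15 rose and 4 fell (16 and 5 adjusted over the list alone), with a median of log2 0.11 and an adjusted p of 0.00383. With an estimated correlation the adjusted p was 0.512. This list was matched by gene symbol, and its called members include a pseudogene, ATP5MC2P4, named after its value was seen. NDUFA9, a subunit of complex I, rose from 0.701 ± 0.408 to 5.06 ± 0.864 (log2 1.85, adjusted p = 0.00253). Its mean at 0 µM lay under the minimum of 1 set for testing. Its log2 fold change against 0 µM was 2.42 at 0.5 µM and 2.46 at 3 µM, so it did not grow with each dose. NDUFS5 rose by log2 0.36 and ATP5PD by 0.28, while ATP5F1B, chosen after its value was seen, fell by 0.48. The number of respiratory chain genes higher was 7 and 9 without replicates 2 and 3 of 10 µM, and the number lower was 2 without replicate 1 of 0 µM or any replicate of 10 µM. None of RPL36, RPS15A, RPL26, NDUFA9, NDUFS5, ATP5PD and ATP5F1B was called with only the 6 compared libraries in the fit. The median longest transcript was 1842 bases in the ribosomal list and 1377 in the respiratory list against 3162 over the genes tested. With each library's trend with transcript length removed, the 2 lists had adjusted p of 0.0501 and 0.0638, with medians of log2 0.20 and 0.11.

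The pluripotency factors SOX2, POU5F1 and NANOG did not pass the test at 10 against 0 µM. SOX2 was 219 ± 20.5 (SD, n = 3) at 0 µM and 201.5 ± 2.76 at 10 µM (log2 -0.12, adjusted p = 0.319). POU5F1 was 3274 ± 399 and 3852 ± 412 (log2 0.24, adjusted p = 0.146). NANOG was 2.63 ± 1.39 and 1.04 ± 0.495 (log2 -0.79, adjusted p = 0.0971), and passed without replicate 3 of 0 µM (adjusted p = 0.0336). These NANOG values lay near the minimum of 1 set for testing, where a log2 change of value + 1 understates the ratio of means. Of 23 core pluripotency genes, 3 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.429, with a median of log2 -0.01, which was 0.13 after median-of-ratios scaling). Only 1 of them rose without replicate 1 of 0 µM or replicate 1 or 2 of 10 µM. The de novo DNA methyltransferase DNMT3B rose from 392 ± 10.7 to 537 ± 5.53 (log2 0.45, adjusted p = 0.00141), and PRDM14, a repressor of differentiation genes, fell by 1.19; DNMT3B and PRDM14 were chosen after their values were seen, and with only the 6 compared libraries in the fit neither was called.

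The 8 highest log2 fold changes named by the fixed rule at 10 against 0 µM ran from 3.23 to 5.48 and belonged to TNFRSF12A, GPI, TARDBP, MT1X, MT1G, GTF2H3, MT1H and MT1E. The 8 lowest ran from -6.55 to -3.04 and belonged to CCNB2, EXOC7, CCAR1, ABI2, RCC1, JAM3, PSMC6 and NCAPG2. Of these 16 genes 14 jumped at least 4-fold between libraries of a dose. The calls of 7 were lost in most of the 6 fits that left out a compared library. TNFRSF12A and CCNB2, the highest and the lowest, lost theirs in each of these 6 fits. CCNB2, a mitotic cyclin listed at a mean of 153 at 0 µM and 0.644 ± 0.143 (SD, n = 3) at 10 µM, was at 50.9 ± 84.9 at 3 µM. Among genes without such jumps, chosen after their values were seen, CYP2B6 fell from 19.3 ± 5.04 to 1.65 ± 0.461 (log2 -2.92, adjusted p = 0.000638), C1QTNF6 fell from 13.2 ± 2.42 to 1.52 ± 0.728 (adjusted p = 0.000677), the neurosecretory gene VGF fell from 109 ± 56.1 to 15.2 ± 3.86 (adjusted p = 0.00412), and P2RX2, an ATP-gated channel, rose from 1.19 ± 0.367 to 6.64 ± 1.06 (adjusted p = 0.00186). The VGF call was lost with only the 6 compared libraries in the fit (adjusted p = 0.0878).

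In all, limma called 2126 of 13815 genes at 10 against 0 µM, 608 higher and 1518 lower (71.4% lower), of which 139 were at least 2-fold higher and 268 at least 2-fold lower. At an unadjusted p under 0.05 there were 4351 genes. Groups did not overlap for 34.1% of the genes tested, where chance gives 10% for 3 against 3. The median log2 fold change over all genes was -0.10, and 0.01 after median-of-ratios scaling, which called 1029 genes higher and 1030 lower, 1638 of them among the 2126. Among called genes in the third with the shortest transcripts, 42.0% were lower, against 90.8% in the third with the longest. With only the 6 compared libraries in the fit, 46 genes were called, 34 of them among the 2126 and MT1X one of these. The count was 1240 without replicate 1 of 0 µM, and 1074, 1154 and 1122 without replicates 1, 2 and 3 of 10 µM.

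The comparison of 3 with 0 µM asked whether the differences were present at a lower dose. MT1X rose from 45.3 ± 21.9 (SD, n = 3) to 394 ± 41.4 (log2 3.20, SE 0.30, adjusted p = 0.00157), MT2A from 50.7 ± 18.7 to 155 ± 3.17 (log2 1.67, adjusted p = 0.0126) and MT1G by log2 3.14. The other members called were MT1H and MT1E, whose calls were lost without replicate 1, 2 or 3 of 3 µM (adjusted p from 0.0593 to 0.0684). In all, 5 of 8 metallothioneins rose (camera adjusted p = 1.59e-05; 0.555 with an estimated correlation as adjusted p). SLC30A1 rose from 3.91 ± 0.377 to 8.54 ± 0.282 (log2 0.96, adjusted p = 0.00494). With only the 6 compared libraries in the fit, MT1X was called and MT2A, MT1G, MT1H, MT1E and SLC30A1 were not (adjusted p = 0.126, 0.129, 0.154, 0.154 and 0.0814). No importer of the ZIP family passed over all genes (4 fell adjusted over the list alone); SLC39A6 was at 22.3 ± 1.33 (log2 -0.48, adjusted p = 0.0721) and SLC39A7 at 0.858 ± 0.121 (log2 -0.57, adjusted p = 0.0502).

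Lists of the unfolded protein response, p53 targets and the lysosome passed as lower at 3 against 0 µM. The unfolded protein response passed camera at an adjusted p of 0.0452 (0.555 with an estimated correlation as adjusted p) with 3 of 18 genes lower and none higher (6 lower adjusted over the list alone, and 6 lower over all genes without replicate 3 of 0 µM). HSPA5 fell by 0.67 on the log2 scale, from 336 ± 46.9 (SD, n = 3) to 209.6 ± 5.94 (adjusted p = 0.00553), and PDIA4 fell by 0.52 (adjusted p = 0.00589). The p53 targets passed at 0.0354 (adjusted p = 0.555 with an estimated correlation) with 2 of 23 lower (3 adjusted over the list alone), SESN2 and BAX; SESN2 and BAX both lost their calls in 5 of the 6 fits that left out 1 compared library, with adjusted p from 0.058 to 0.143, while 6 p53 targets fell without replicate 3 of 0 µM. The lysosome list passed at 0.0452 (adjusted p = 0.713 with an estimated correlation) with 5 of 22 lower (6 lower and 1 higher adjusted over the list alone). Without replicates 1 and 2 of 0 µM 2 fell, and without replicates 1, 2 and 3 of 3 µM 1, 1 and 2 fell. LEFTY1, NODAL and GSC, chosen after their values were seen, fell by 1.96, 0.92 and 1.77 on the log2 scale. The calls of HSPA5, PDIA4, SESN2, BAX, LEFTY1, NODAL and GSC were lost with only the 6 compared libraries in the fit. The ribosomal list (adjusted p = 0.0452, median log2 0.10, no member called) and the mitochondrially encoded list (adjusted p = 0.0495, median log2 0.24, no member called) passed as higher. With an estimated correlation their adjusted p were 0.799 and 0.868. Without replicate 3 of 0 µM, RPL36, RPL38, RPL39 and RPL26 were called as higher (adjusted p = 0.0157, 0.0277, 0.028 and 0.0175). With the length trend removed, the lysosome, ribosomal and mitochondrially encoded lists had adjusted p of 0.0725, 0.244 and 0.382.

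At 3 against 0 µM the largest changes named by the rule were MCRS1, TARDBP, GSTK1 and SMC2, higher by log2 4.95, 4.37, 3.75 and 3.65, and C12orf75, MRPL21, SYNE2 and STIMATE, with log2 fold changes of -4.49, -3.47, -2.93 and -2.86. Of these 8 genes 6 jumped at least 4-fold within a dose. Calls of 3 (TARDBP, SMC2 and C12orf75) were kept in each fit that left out 1 compared library. TARDBP lost its call with only the compared libraries in the fit (adjusted p = 0.12). For SMC2 and C12orf75 the 3 µM libraries also differed from those at 0.5 and 10 µM. SOX2, POU5F1 and NANOG did not pass (adjusted p = 0.0854, 0.296 and 0.605). SOX2 passed as lower without replicate 3 of 0 µM (log2 -0.31, adjusted p = 0.0131). In all, limma called 982 genes, 405 higher and 577 lower, and 3622 at an unadjusted p under 0.05; median-of-ratios scaling called 560 higher and 522 lower. With only the 6 compared libraries in the fit 43 genes were called. The count was 397, 473 and 2086 without replicates 1, 2 and 3 of 0 µM and 169, 223 and 227 without replicates 1, 2 and 3 of 3 µM.

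The 10 µM and 3 µM responses overlapped, and shared the 3 libraries at 0 µM. At both doses, 299 genes were higher and 505 lower, including MT1X, SLC30A1, LEFTY1 and HSPA5, and none changed in opposite directions. Across genes, the log2 fold changes correlated at r = 0.68, against 0.50 in 50 simulations in which the shared libraries alone link the comparisons. The simulations drew each gene independently, with the same spread at every dose. Genes that vary together and a wider spread at 0 µM could also raise r. The gap therefore does not show a response beyond the shared libraries.

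The comparison of 0.5 with 0 µM asked what the lowest dose changed. Metallothioneins were again higher in camera: the 8-gene list passed (adjusted p = 0.0103, median log2 1.09, and adjusted p = 0.709 with an estimated correlation). Adjusted over the list alone 5 members rose, although no single member passed over all genes. No list passed fry at 0.5 against 0 µM. MT1X was 45.3 ± 21.9 (SD, n = 3) at 0 µM and 127 ± 20.8 at 0.5 µM (log2 1.57, adjusted p = 0.0638), and passed without replicate 3 of 0 µM (adjusted p = 0.00759). SLC30A1 was 3.91 ± 0.377 and 4.68 ± 0.628 (adjusted p = 0.401). NDUFA9 rose by log2 2.42 (adjusted p = 0.00707) and VPS51, a tethering factor of endosomal traffic, rose from 5.54 ± 2.80 to 46.9 ± 3.71 (log2 2.98, adjusted p = 0.00778); both calls held in each of the 6 fits that left out 1 compared library and were lost with only the compared libraries in the fit. CACNB1, chosen after its values were seen, rose by log2 1.61 (adjusted p = 0.00247).

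Of the other genes named by the rule at 0.5 against 0 µM, TARDBP and RHNO1 rose by log2 4.43 and 2.53, and VGF, ACTC1 and PNMA2 fell by 2.33, 1.94 and 1.85. TARDBP lost its call without replicate 1, 2 or 3 of 0.5 µM (adjusted p = 0.0765, 0.0836 and 0.104). RHNO1, VGF, ACTC1 and PNMA2 lost theirs in most of the 6 fits that left out 1 compared library. The ribosomal list passed camera as higher (adjusted p = 0.0103, median log2 0.14), and the p53, YAP and ATF4 lists as lower (adjusted p = 0.0171, 0.0462 and 0.0462, medians of log2 -0.36, -0.22 and -0.22). No ribosomal, p53, YAP or ATF4 member passed over all genes, and 3 ATF4 targets fell adjusted over the list alone. Without replicate 3 of 0 µM some members passed, among them RPL36, SESN2, STC2 and CCN2 (adjusted p = 0.0272, 0.00971, 0.02 and 0.0102), but not BAX or PLK2. All 4 lists had an adjusted p of 0.709 with an estimated correlation. With the length trend removed, the ribosomal, YAP and ATF4 lists each had an adjusted p of 0.0576. SOX2, POU5F1 and NANOG did not pass (adjusted p = 0.149, 0.193 and 0.557). SOX2 passed as lower without replicate 3 of 0 µM (log2 -0.32, adjusted p = 0.0222). In all, limma called 47 genes, 25 higher and 22 lower, and 2510 at an unadjusted p under 0.05. The fit of only the 6 compared libraries called 17 genes, 0 of them among the 47, and the count was 18 and 968 without replicates 2 and 3 of 0 µM and 12, 11 and 8 without replicates 1, 2 and 3 of 0.5 µM.

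Between 0.5 and 3 µM, no list passed fry, and the step was visible in metallothioneins as a list in camera. The list passed camera (adjusted p = 9.5e-07, median log2 0.92; adjusted p = 0.568 with an estimated correlation) and 4 members rose adjusted over the list alone, while MT1X, at 127 ± 20.8 (SD, n = 3) and 394 ± 41.4, did not pass over all genes (log2 1.63, adjusted p = 0.236), but passed with only the compared libraries in the fit (adjusted p = 0.041). SLC30A1 was 4.68 ± 0.628 and 8.54 ± 0.282 (log2 0.75, adjusted p = 0.123), and passed adjusted over the list alone. The mitochondrially encoded list passed as higher (adjusted p = 4.27e-09, median log2 0.28, no member called; adjusted p = 0.652 with an estimated correlation), and the unfolded protein response as lower (adjusted p = 0.00929, median log2 -0.22, no member called, 2 lower adjusted over the list alone; adjusted p = 0.568 with an estimated correlation). In all, limma called 4 genes and 768 at an unadjusted p under 0.05. SMC2, a condensin subunit, rose from 0.0136 ± 0.00721 to 13.8 ± 5.03. C12orf75 fell from 25.0 ± 2.39 to 0.201 ± 0.102, UBE2M, a NEDD8-conjugating enzyme, from 80.5 ± 1.93 to 40.0 ± 2.27, and ARRDC4 from 18.9 ± 0.229 to 11.8 ± 0.669. The signal of a gene may belong to different transcripts at different doses, which was not tested. The rule for unstable genes compares libraries within a dose, so it cannot show this. The ARRDC4 call was lost without replicate 1, 2 or 3 of 0.5 µM and without replicate 1 of 3 µM (adjusted p = 0.0631, 0.0847, 0.0815 and 0.0637), and with only the compared libraries in the fit (0.0681). The count was 10 and 8 without replicates 1 and 2 of 0.5 µM, 9, 11 and 14 without replicates 1, 2 and 3 of 3 µM, and 18 with only the compared libraries.

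Between 3 and 10 µM, the metallothionein list passed camera as higher (adjusted p = 0.00365, median log2 0.55, and adjusted p = 0.806 with an estimated correlation), with no member called. No list passed fry at 10 against 3 µM. MT1X was 394 ± 41.4 (SD, n = 3) and 633 ± 103 (log2 0.67, adjusted p = 0.635). SLC30A1 was 8.54 ± 0.282 and 8.48 ± 0.942 (log2 -0.01, adjusted p = 0.987). The nuclear respiratory chain list (adjusted p = 0.00365, median log2 0.06) and the replication-dependent histones (adjusted p = 0.0182, median log2 0.09) passed as higher with no member called; with an estimated correlation their adjusted p were 0.806 and 0.331. With the length trend removed the histone list had an adjusted p of 0.0842. In all, limma called 6 genes and 1061 at an unadjusted p under 0.05. C12orf75, UBE2M, HIVEP1 and ZNF341 rose by log2 4.47, 1.14, 2.17 and 1.58, and SMC2 and ARHGEF25 fell by 3.77 and 2.45; HIVEP1 and ZNF341 lay outside the rule and were chosen after their values were seen. The ARHGEF25 call was lost without replicate 2 of 3 µM and replicates 1 and 2 of 10 µM (adjusted p = 0.0614, 0.0831 and 0.0737), and the ZNF341 call without replicates 2 and 3 of 3 µM and 1 and 2 of 10 µM (0.1, 0.121, 0.186 and 0.136). With only the compared libraries in the fit both were lost, and after median-of-ratios scaling or removal of the length trend so was ZNF341. For C12orf75, UBE2M and SMC2 the 3 µM libraries differed from both neighbouring doses. Whether another transcript of these genes was listed at 3 µM was not tested. The count was 14 without replicate 3 of 3 µM, 10 and 13 without replicates 2 and 3 of 10 µM, 16 with only the compared libraries, and 2 with a minimum of 5.

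Across the 4 doses the F-test of limma called 721 genes, and 3574 at an unadjusted p under 0.05. Among the 721, the group means of 110 genes rose at every step and those of 366 fell at every step, with no chance level set for these counts. MT1X (adjusted p = 0.00149) and SLC39A6 (adjusted p = 0.0485) moved in 1 direction at every step. The count ran from 185 without replicate 3 of 10 µM to 1506 without replicate 3 of 0 µM.

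**Figure D3:**
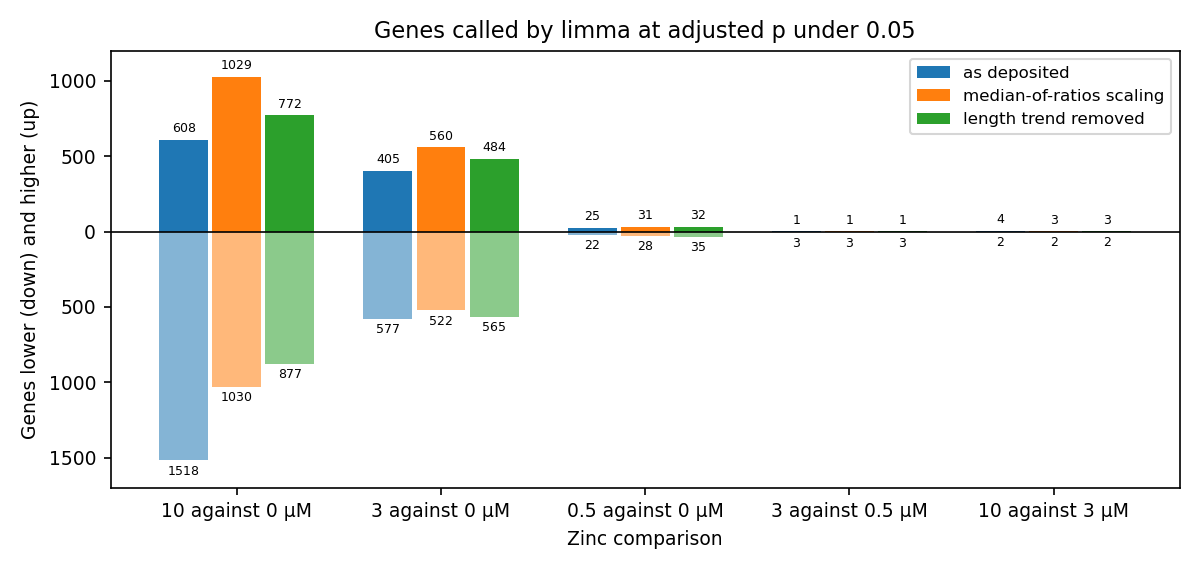
Genes called by limma at an adjusted p under 0.05 in each zinc comparison, higher above 0 and lower below, as deposited, after median-of-ratios scaling and with the length trend removed. At 10 against 0 µM the split is 608 and 1518 as deposited, 1029 and 1030 after scaling, and 772 and 877 with the length trend removed. Scaling and trend removal both centre the typical gene near 0 (median log2 0.01 in each), so their near-even splits do not show why more genes were lower.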

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

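Alternatives added after seeing the data were blanks read as 0, only genes within 4-fold in every group, only genes with 1 annotated transcript, library weights and removal of the length trend. No called gene put through these and the fixed alternatives changed sign. More genes became higher than lower at 3 against 0 after median-of-ratios scaling (560 and 522) and with only genes with 1 transcript (229 and 213), and more became lower than higher at 0.5 against 0 with no filter (23 higher, 28 lower), with the length trend removed or library weights (32 and 35 in both) and without replicate 3 of 0 µM (426 and 542). With only the compared groups in the fit, counts against 0 µM were 46 at 10, 43 at 3 and 17 at 0.5 µM. The steps gave 18 at 3 against 0.5 and 16 at 10 against 3, and 5 lists passed at 10 against 0. This fit has fewer libraries to estimate the spread from. The fit of all libraries shares 1 spread over the doses, although the 0 µM libraries lay further apart on the first principal component. It can thus understate the error of comparisons with 0 µM. Which of the 2 moved the counts was not tested. With the replicate number as a block, counts were 592 at 3 against 0, 13 at 0.5 against 0, 246 across the doses and 5 lists; the 10 against 0 count was 1777. A minimum of 5 gave 2 genes at 10 against 3, and limma without a trend gave 7 at 3 against 0.5. Lists passing at 10 against 0 were 5 with a pseudocount of 5, 5 with no filter, 8 after median-of-ratios scaling (4 higher, 4 lower), 0 with an estimated correlation, 9 with only genes within 4-fold (4 higher, 5 lower), 5 with library weights and 4 with the length trend removed (1 higher, 3 lower), of which 1 is among the 3 reported, all higher. Only genes within 4-fold gave 1509, 149 and 11 genes at 3 against 0, 0.5 against 0 and 3 against 0.5, and 1370 across the doses; noisier genes are then outside the adjustment. Only genes with 1 transcript gave 628, 442, 141, 1 and 0 genes in the order above and 442 across the doses, from fewer genes tested. Library weights gave 18 at 3 against 0.5. Leaving out 1 library gave ranges of 1074 to 2798 at 10 against 0, 169 to 2086 at 3 against 0, 8 to 968 at 0.5 against 0, 3 to 14 at 3 against 0.5, 8 to 14 at 10 against 3, 185 to 1506 across the doses and 3 to 5 lists; for the other moved counts the cause was not tested. At 10 against 0, the other alternatives gave 1649 to 2604 genes. Of 48 genes put through the alternatives there, 35 lost their call with only the compared groups. SOX2, POU5F1 and NANOG are among the 48 and had no call to lose. MT1X, CYP2B6, C1QTNF6, P2RX2 and ABI2 kept their calls in every alternative run on them. ABI2 jumped at least 4-fold within a dose, so the alternative with only genes within 4-fold was not run on it. The alternatives planned for Basic03 were not run, and for the F-test a fit of only its groups is the fit reported. Depth is unknown, so its limit on these calls could not be set.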

Other observations

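The tests of 1 transcript model per gene, of low values, of a change of transcript model, and of carried-over zinc and gene length in the 0 µM libraries were chosen after the result was seen, as were the genes named in this part. At 10 against 0 µM, antiviral sensors were lower and a tethering factor higher among 9 interferon response genes, of which 1 rose and 3 fell (camera adjusted p = 0.717). DDX58, an RNA sensor, fell from 13.8 ± 2.44 (SD, n = 3) to 6.92 ± 0.430 (log2 -0.89, adjusted p = 0.00312), IFIH1 fell by 0.90, and BST2, which holds virions at the cell surface, rose from 16.2 ± 7.22 to 44.2 ± 2.54 (log2 1.49, adjusted p = 0.0101). SIX3 and SIX6, transcription factors of the anterior brain and eye, fell from 10.8 ± 1.66 to 4.07 ± 0.553 (adjusted p = 0.0025) and from 31.5 ± 2.32 to 17.8 ± 2.19 (adjusted p = 0.00708); FABP7, in the same list of 15 neuroectoderm genes, rose (adjusted p = 0.00884), and the list had a camera adjusted p of 0.223. SLC31A1, the main copper importer, fell from 29.1 ± 4.80 to 18.3 ± 0.650 (adjusted p = 0.00746). MKI67, a marker of cycling cells, fell from 48.2 ± 8.90 to 27.5 ± 2.25 (adjusted p = 0.00534), with 8 of 31 genes of G2 and M phase lower and 1 higher (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.223). The number lower was 4 without replicate 1 of 0 µM and 2, 3 and 5 without replicates 1, 2 and 3 of 10 µM, and the higher call was lost in 5 of the 6 left-out fits.

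Several genes chosen for their size of change stepped with dose. ERVH48-1, an endogenous retroviral envelope gene, was 71.2 ± 7.79 (SD, n = 3) at 0 µM, 36.6 ± 4.95 at 0.5 µM, 20.9 ± 0.520 at 3 µM and 20.1 ± 0.627 at 10 µM, and fell at 0.5, 3 and 10 against 0 µM (adjusted p = 0.0152, 0.00014 and 0.000205). GNA14, a G protein subunit, was 92.5 ± 11.7, 55.7 ± 0.485, 40.1 ± 1.56 and 35.2 ± 2.41, and fell in the same 3 comparisons (adjusted p = 0.0217, 0.000468 and 0.000333). RPRM, a mediator of cell cycle arrest, had a mean of 84.2 at 0 µM, then 41.0 ± 6.63, 23.4 ± 0.797 and 22.4 ± 3.70, and fell at 3 and 10 µM (adjusted p = 0.00212 and 0.00135). The small GTPase gene RRAS was 9.82 ± 2.18, 19.0 ± 1.24, 23.9 ± 0.876 and 30.1 ± 1.35 and rose at 0.5, 3 and 10 against 0 µM (adjusted p = 0.0316, 0.0028 and 0.000677). TXNIP and ARRDC4, arrestin-family genes that respond to glucose, fell at 10 against 0 µM (adjusted p = 0.00291 and 0.000495). The calls at 10 against 0 µM of ERVH48-1, GNA14, RPRM, RRAS, TXNIP and ARRDC4 held when any 1 of the 6 compared libraries was left out, and so did those of DDX58, IFIH1, BST2, SIX3, SIX6, FABP7, SLC31A1 and MKI67. With only the 6 compared libraries in the fit, ERVH48-1, GNA14, RPRM, RRAS and ARRDC4 were called at 10 against 0 µM and the others named here were not. That fit did not call RRAS at 3 against 0 µM, nor ERVH48-1, GNA14 or RRAS at 0.5 against 0 µM. At 0.5 against 0 µM the ERVH48-1 call was lost without replicate 3 of 0.5 µM (adjusted p = 0.0559), and the GNA14 and RRAS calls without replicate 2 of 0 µM (0.0505 and 0.0741) or any replicate of 0.5 µM (0.075 to 0.0935 and 0.0834 to 0.128).

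Values of 2241 of 13815 genes jumped at least 4-fold between libraries of 1 dose. The jumps were not confined to low values, where sampling noise is largest: of 2959 genes with a mean of 20 or more, 317 (10.7%) jumped. Among protein-coding genes with 1 annotated transcript 1.14% jumped, against 20.2% of the others, and the share went up through 5.83%, 13.5%, 19.5%, 27.7% and 37.0% as the number of transcripts grew. A candidate explanation is that the table may list the value of 1 transcript model per gene, with another model in another library; ribosomal protein genes, whose median was 299, were listed as low as 1.77. No biological explanation was tested, since the design gives none within a dose.

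More genes were lower than higher at 10 against 0 µM (71.4% of the calls). A change of transcript model as the whole cause would leave no excess of lower calls among genes with 1 transcript. There, 261 of 427 called genes (61.1%, exact 95% interval 56.3 to 65.8) were lower, which goes against that cause without settling it. The interval treats genes of the same 6 libraries as independent, so it may be too narrow. Transcript length could account for part of it: 42.0%, 76.0% and 90.8% of calls were lower in the shortest, middle and longest of 3 length classes. Library composition cannot be told apart, because median-of-ratios scaling, which gave 50% lower, centres the typical gene at 0; leaving out mitochondrial genes and setting the other values to equal sums gave 70.0% lower, which speaks against the mitochondrial share alone, a further test chosen after the first was seen. The length trend itself went with dose, with slopes of 0.089, 0.016 and 0.022 in log2 per doubling of length at 0 µM and -0.03, -0.057 and -0.037 at 10 µM, so an effect of zinc on long transcripts stays open and was not tested.

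The 3 libraries at 0 µM spread on the first principal component more than those of the other doses, at -70.1, -41.8 and -19.8. Gene length and library composition as the whole cause are argued against: the range was 100% of its deposited value with the length trend removed and 92.4% after median-of-ratios scaling. Zinc carried into some 0 µM libraries cannot be told apart from other differences between them. The difference of replicates 3 and 1 correlated with 10 against 0.5 µM across genes at r = 0.175, that of replicates 2 and 1 at 0.237 and that of replicates 3 and 2 at -0.045, against -0.008, -0.008 and 0 for pairs at 3 µM; the metallothionein sums of replicates 1 to 3 were 151, 97.5 and 266, so neither r nor the order on the component followed them, but these are single libraries. The condition on that order was added after r was seen, and without it the test would have been met; no biological explanation was tested.

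Splits of the same 6 libraries into 3 and 3, the real one included, number 10, too few for a share under 0.05. At 10 against 0 µM the real split called 2126 genes, reached by 1 split, and the highest other split 5; for lists the real split passed 3, reached by 4 splits, and the highest other 3. At 3 against 0 µM it called 982 (1 split) and the highest other 9, and at 0.5 against 0 µM 47 (1 split) and 7. At 3 against 0.5 µM it called 4, reached by 7 splits, with 6 as the highest other, and at 10 against 3 µM 6, reached by 3 splits, with 8. Across the 4 doses, 1 of 100 drawn splits of the 12 libraries, the real one, called as many as 721 genes. The highest other called 38, which argues against a random assignment of independent libraries. The labels do not say whether libraries of a dose were cultured separately, so a difference between cultures cannot be excluded.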
